A study of Mus musculus with 15 samples.

How the data were processed

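Gene expression was measured in 15 samples of sorted mouse liver macrophages, 5 in each of 3 groups, on Agilent one-colour (Cy3) mouse arrays lying on 2 slides. Per the labels, the Western diet began at 8 weeks of age and was fed for 20 weeks (the age of the wildtype mice is not given in the sources used here), RNA of each sample was pooled from 7 to 9 mice and 0.1 ug of it was labelled. Per the file headers, the scanner files hold the intensity of each spot (processed signal, background-subtracted and spatially detrended, not scaled between arrays, from Agilent Feature Extraction 10.7.3.1) and other columns of flags per spot. The deposited table holds log2 values, which were found to be the log2 processed signal minus the 75th percentile of the array minus the median of the wildtype arrays (median absolute difference 0.00146, above 0.00469 for 1%). It was used only as an alternative.

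Of 62976 spots on an array, 3671 control spots were left out, as were spots marked as outliers by the scanner software (113 to 190 per array). No spot was saturated. The log2 processed signal was taken, the 75th percentile of the array's non-control probes was subtracted, and repeated spots of a probe were averaged. Probes were named through their RefSeq accessions with the table of the mouse genome GRCm38, without coordinates. Of 55681 probes 26582 were named, for 20145 genes, and 29099 were not. Probes were kept when well above background in at least 4 of 5 arrays of at least 1 group, which left 28175 (17342 named), and the probe with the highest mean stood for its gene. That gave 13390 genes, of which 3329 had more than 1 kept probe and 12 had a missing value. The number of arrays limits the precision.

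Groups were compared with lmFit and eBayes of limma 3.58.1 (R 4.3.3, with data.table in version 1.17.8) on all 15 arrays with group means and no covariates, 2-sided, at a Benjamini-Hochberg adjusted p under 0.05 over the genes of a comparison. A fold change against a group in which no array was well above background is given as a lower bound. It was computed against the lowest signal called well above background on each array, or the gene's own value where higher. Such a bound holds for the main processing only. Over the alternatives below, Prok2 went down to 2.145 log2 in NASH CD11c-negative against wildtype cells, under its bound of 3.35. The same was done, after the results were seen, where only 1 or 2 arrays of the lower group were well above background, with their values kept where higher. In all, 33 gene lists (20 of functions, 13 of other cell types; 459 of 499 genes measured) were set against the other genes with limma camera and an estimated correlation, adjusted over the 31 lists with at least 4 measured genes. Of 480 list memberships measured, 437, 360 and 440 passed over all genes and 440, 369 and 443 adjusted over the list alone (NASH CD11c-negative against wildtype, CD11c-positive against CD11c-negative, CD11c-positive against wildtype). With a preset correlation of 0.01, 22, 17 and 18 lists were called, and with the estimated correlation 3, 3 and 1. Fry, which asks whether a list moves on balance in a direction and does not compare it with other genes, called 30, 29 and 30. The median, the mean and the direction of the set test did not all have the same sign for 2, 5 and 5 lists. These were phagocytic receptors and complement in the first comparison. In the second they were class II, alternative activation, the unfolded protein response, plasmacytoid dendritic cells and B cells. In the last they were complement, plasmacytoid dendritic cells, stellate cells, natural killer cells and platelets.

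The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, per comparison, the 5 largest rises and 5 largest falls among genes that passed without overlap between the groups (predicted genes and receptor segments left out), the 2 members of each function list with the largest change and the largest in the opposite direction, the 2 brightest members of each other list called, and Itgax, Adgre1 and Mc4r. Clec4f, Trem2, Flt3, Ccr7, Cd209a, Camp, Ltf and Csf3r were named after their values were seen, as were further values of genes that the rule named in another comparison. A few of the genes that the rule names are not reported here, although the counts include them. In all, 222 pairs of a gene and a comparison were followed through the alternatives.

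The alternatives were normexp background correction (offset 50, on median spot and background intensity since the files hold no mean signal), quantile normalization, no filter, a filter on all 15 arrays, slide as a block or each slide alone, replicate number as a block with and without slide, only the groups compared, the mean of a gene's probes, a trended and robust prior, array weights, the deposited values, and each array left out. The counts of genes changed at least 2-fold under these alternatives were added after the data were seen. The neutrophil test was first run on the 7 members at least 4-fold higher in NASH CD11c-negative than in wildtype cells, and then on all 11 with the same bounds. The analysis was tested on simulated data of 13378 genes with 200 changed. It recovered 54% to 56% of changes of 0.25, 78% to 80% of 0.5, 94% to 96% of 1 and 100% of 2 log2 units, 4.57% to 6.09% of calls were unchanged genes, and the planted list was found with 0 other lists called. The simulated genes varied independently and without a slide effect, and far fewer were changed than were called in the data. The simulation therefore does not test the list calls, since genes of a list vary together in the data (estimated correlation 0.55 for the lysosome list, the one planted). Unnamed probes were not used in the comparisons.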

Results

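The expression of genes in resident liver macrophages was measured on 15 one-colour mouse microarrays. Livers came from wildtype mice on standard chow and from mice without the melanocortin 4 receptor (MC4R), a receptor of the brain that restrains food intake, which had eaten a Western diet for 20 weeks and had non-alcoholic steatohepatitis (NASH). Liver macrophages with high F4/80 were sorted further by CD11c, the integrin alpha X chain used to mark dendritic cells and lipid-laden or inflammatory macrophages. The 3 groups were CD11c-negative cells of wildtype livers (below, wildtype), CD11c-negative cells of NASH livers and CD11c-positive cells of NASH livers, with 5 arrays each. The RNA of each sample was pooled from 7 to 9 mice. The 75th percentile of the signal ranged from 358.6 to 562.4 units between arrays, and 45.8% to 58.0% of the spots of an array were well above background. In all, 13390 genes were tested. Fold changes are differences of mean log2 values ± the limma standard error, with n = 5 arrays per group.

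The 3 groups were far apart compared with the arrays within them. The median standard deviation of a gene between the 5 arrays of a group was 0.0751 for wildtype, 0.0888 for NASH CD11c-negative and 0.0700 for NASH CD11c-positive cells (log2). The leading principal component held 67.3% of the variance between arrays and the next held 16.4%. Spots of a probe repeated on a single array differed by a median SD of 0.0474 to 0.0610, and a spot differed between the arrays of a group on the same slide by 0.0348 to 0.0390. The arrays are labelled as separate samples, but nothing says that they came from separate pools of mice. All p-values therefore measure only the spread between these samples, which may be technical, and the size of each change is given ahead of its test.

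Mc4r, the deleted gene, had 1 probe, which was not well above background on any of the 15 arrays (normalized log2 values from -7.18 to -3.85). It gave no level in these cells and does not check the genotype. Itgax, which encodes CD11c, was lowest in wildtype cells (4.21), higher in NASH CD11c-negative cells (5.93) and highest in NASH CD11c-positive cells (7.29), so the cells sorted as negative also differed, by 1.72 ± 0.033. Adgre1, which encodes F4/80, stood at 7.34, 7.74 and 7.31 in the same order. The higher Adgre1 of the NASH CD11c-negative cells (0.40 ± 0.033) depended on the scaling, with -0.06 after quantile normalization.

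**Figure D1:**
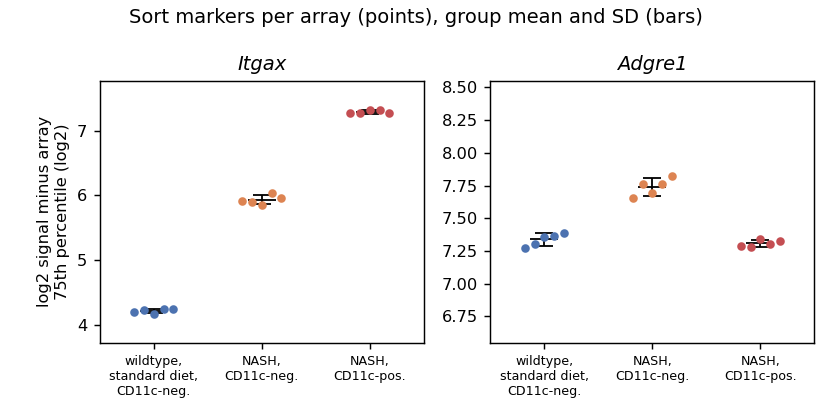
Level of the sort markers Itgax (CD11c) and Adgre1 (F4/80) on each array, as log2 signal minus the array's 75th percentile; points are arrays, bars the group mean and SD over 5 arrays. Itgax stepped up from 4.21 in wildtype to 5.93 and 7.29 in the NASH groups, whereas the Adgre1 means stayed between 7.31 and 7.74.

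The comparison of NASH CD11c-negative with wildtype cells asks how macrophages without CD11c differ between diseased and healthy livers. Cd163, the scavenger receptor for haptoglobin-bound haemoglobin, was 29.4-fold lower in NASH (-4.88 ± 0.049 log2, n = 5 per group), and Timd4, a phosphatidylserine receptor of long-lived resident macrophages, was 7.48-fold lower (-2.90 ± 0.036). Spp1, which encodes osteopontin, was 13.7-fold higher (3.78 ± 0.043) and the tetraspanin gene Cd63 9.14-fold higher (3.19 ± 0.029). Genes of neutrophil granules were among the largest rises, with Mpo (myeloperoxidase) 47.9-fold (5.58 ± 0.038) and Ngp 38.3-fold higher (5.26 ± 0.044). At least 2-fold changes were found for 694 genes upward and 833 downward, of which 157 and 190 changed at least 4-fold.

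Among the 5 largest rises by fitted value, Mogat2, a monoacylglycerol acyltransferase, Prok2, a secreted prokineticin, and Ctsj, a cathepsin, were not well above background on any wildtype array, so only bounds can be given. They were at least 13.6-fold, 10.2-fold and 8.01-fold higher in NASH CD11c-negative cells with the main processing. Over the alternatives they went down to 2.358, 2.145 and 2.137 log2, under these bounds. Among the 5 largest falls by fitted value, Adra2c, an adrenergic receptor gene, and Gpr141b, an orphan receptor gene, were not well above background on any NASH CD11c-negative array and were at least 11.9-fold and 11.9-fold lower there. The prostacyclin synthase gene Ptgis fell by 4.59 (SE 0.0532). Sdc2, a heparan sulphate proteoglycan gene, was well above background on only 2 of the 5 NASH arrays and was at least 30.8-fold lower.

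Of the 18 measured genes of Kupffer cell identity, 16 fell, 1 rose and 1 did not pass. The median member changed by -1.05, or -1.18 relative to the median of all genes (0.13), and the list as a whole did not pass against the other genes (adjusted p = 0.133, limma camera). Besides Cd163 and Timd4, Clec4f, a lectin restricted to Kupffer cells, fell (-1.22 ± 0.036). The exception was Id3, a transcriptional regulator needed by Kupffer cells (0.60 ± 0.052, but 0.13 with quantile normalization). All 12 genes of the lipid-associated macrophage list rose, 11 of them at least 2-fold (list median 2.48, adjusted p = 0.0834). They included Trem2, a lipid-sensing receptor gene (2.63 ± 0.037), and Fabp5, a fatty acid binding protein gene (2.46 ± 0.026). Clec4f, Trem2 and the further genes Flt3, Ccr7, Cd209a, Camp, Ltf and Csf3r were named after their values had been seen.

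Genes of lipid handling mostly rose, while genes at large also rose more often than they fell (6466 higher and 3814 lower of 13390). In the list of lipid uptake and storage, 14 of 16 genes rose and 1 fell, among them Angptl4, an inhibitor of lipoprotein lipase (2.61 ± 0.039). In the other direction went Scarb1, a lipoprotein receptor gene (-0.18 ± 0.028, from -0.55 to -0.15 over the alternatives). Of the liver X receptor targets, 10 of 14 rose, led by the cholesterol exporters Abca1 (1.10 ± 0.028) and Abcg1 (1.03 ± 0.030, as low as 0.58 over the alternatives). Mertk, a receptor for apoptotic cells, fell (-0.70 ± 0.030). Of 23 genes of cholesterol biosynthesis, 19 rose and 2 fell. Msmo1 rose by 0.90, and Insig1, which restrains sterol synthesis, fell (-0.71 ± 0.053). The squalene synthase gene Fdft1 gave 0.80 ± 0.046 on its brightest probe but -0.52 on another, and it did not pass when its probes were averaged. Fatty acid oxidation genes moved little, 15 of 18 upward and 1 downward, with Slc25a20, the carnitine carrier, at 0.74 ± 0.075 and Ehhadh, a peroxisomal enzyme gene, at -0.66 ± 0.12. Lysosomal genes rose in 20 and fell in 2 of 27 cases, with Psap at 0.90 ± 0.032 (0.42 with quantile normalization). None of these 5 lists passed against the other genes, with adjusted p between 0.329 and 0.482.

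Inflammatory cytokines and chemokines rose in 16 of 17 cases (list median 0.96). The neutrophil-attracting chemokines Cxcl1 (2.35 ± 0.036) and Cxcl2 (2.11 ± 0.040) rose most, and the exception was Il6, which fell (-1.70 ± 0.039). Of the profibrotic and matrix-remodelling genes, 17 of 19 rose and 1 fell. Timp1, an inhibitor of matrix metalloproteinases, rose (3.02 ± 0.094, as low as 1.67 over the alternatives) together with Spp1, and Pdgfc fell (-0.30 ± 0.041). In the same comparison 10 of 11 neutrophil markers rose, with a median of 2.64. The type I interferon list was mixed, with 16 genes higher, 6 lower and 2 not passed, and with Ifi44 (1.57 ± 0.042) and Bst2 (0.86 ± 0.049, as low as 0.44 over the alternatives) up. Of the Toll-like receptor and inflammasome genes 10 rose, 5 fell and 4 did not pass, with the lipopolysaccharide co-receptor Cd14 at 1.64 ± 0.041, Tlr1 at 1.28 ± 0.038 and Tlr3 at -0.65 ± 0.036. The cytokine, profibrotic, interferon and Toll-like receptor lists did not pass as groups, with adjusted p from 0.213 to 0.756.

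Complement and scavenger genes went both ways. C2 (-2.45 ± 0.047) and C4b (-1.25 ± 0.034), which form the classical-pathway convertase, fell, and the receptor gene C5ar1 rose (1.18 ± 0.027), in a list with 7 genes higher and 4 lower. The list median was 0.30 and turned to -0.16 with quantile normalization. Among phagocytic and scavenger receptors 10 rose and 8 fell, with Clec4e, which encodes the receptor Mincle, at 1.82 ± 0.064. Their median was 0.12, against -0.24 with quantile normalization, and it differed in sign from the direction of the set test. Of 13 iron and haem genes 8 fell, including the haem transporter gene Slc48a1 (-1.48 ± 0.038), and 5 rose, including the iron importer gene Slc11a2 (0.75 ± 0.046). Among alternative activation genes 4 rose and 7 fell, with Chil3, a chitinase-like protein gene also used as a monocyte marker, at 3.33 ± 0.040. Of 13 genes for MHC class II presentation and costimulation 9 rose, led by H2-Aa (1.36 ± 0.029), and 4 fell, led by H2-Ob (-1.88 ± 0.042) and H2-Oa (-1.55 ± 0.065), whose products hold back peptide loading. Adjusted p lay between 0.227 and 0.991 for these 5 lists.

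Stress and growth genes mostly rose, again beside 6466 genes higher and 3814 lower among the 13390 tested. All 16 immediate early and heat shock genes rose (list median 0.79), led by Atf3 (1.79 ± 0.036) and Socs3 (1.46 ± 0.036), a feedback inhibitor of cytokine signalling. The unfolded protein response list had 12 genes higher and 2 lower, with the asparagine synthetase gene Asns at 1.44 ± 0.036 and Chac1 at -1.10 ± 0.049. Of glycolysis and hypoxia genes 15 of 18 rose, among them the lactate exporter gene Slc16a3 (1.10 ± 0.038) and Ldha (0.93 ± 0.037, 0.46 with quantile normalization), and 1 fell, Hk1 (-0.35 ± 0.048), whose other probe gave 0.01 (-0.17 for their mean). Cell cycle genes rose in 24 of 28 cases with a median of 0.31. Tyms, a nucleotide synthesis gene, stood at 0.93 ± 0.13, Pcna, the replication clamp gene, at 0.71 ± 0.030 (0.33 with quantile normalization), and the proliferation marker Mki67 fell (-0.29 ± 0.045). Adjusted p lay between 0.244 and 0.445 for these 4 lists.

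Markers of lymphoid and dendritic cells were lower in the NASH CD11c-negative than in the wildtype cells. The T cell list (12 of 13 fell, median -1.50), the B cell and plasma cell list (8 of 10 fell, median -1.59) and the conventional dendritic cell list (9 of 10 fell, median -1.15) each passed at adjusted p = 0.0302 by limma camera with an estimated correlation. With members not above background in NASH set at their bounds, the medians were -1.47, -1.41 and -1.15, and over the alternatives they shrank to as little as -0.965, -0.71 and -0.92. Icos, a T cell costimulator gene, fell (-2.14 ± 0.039) while Cd3e gave -0.07 ± 0.12 (adjusted p = 0.598), passing only within slide 2 (-0.21). Jchain, of plasma cells, fell (-0.84 ± 0.057) and Cd79b gave -0.04 ± 0.066 (adjusted p = 0.587), passing only with quantile normalization (-0.35). The dendritic cell genes Flt3 (-3.14 ± 0.054), Wdfy4 (-0.84 ± 0.050) and Batf3 (-0.39 ± 0.041) fell. Natural killer genes fell in 8 of 11 cases (adjusted p = 0.133), liver sinusoidal endothelial genes in 14 of 15 (adjusted p = 0.116) and hepatocyte genes in 10 of 15 (adjusted p = 0.227). The neutrophil list did not pass either (adjusted p = 0.0834), but it was called with normexp (median 2.63), quantile normalization (2.13), no filter or slide as a block (2.64 each), and without NASH CD11c-negative replicate 5 (2.61). Camp (5.19 ± 0.045) and Ltf (5.13 ± 0.039) rose with Mpo and Ngp, and the receptor gene Csf3r fell (-0.40 ± 0.027). Monocyte markers rose in 10 of 13, stellate cell markers in 7 of 11, plasmacytoid dendritic cell markers in 2 of 6 and platelet markers in 3 of 4 cases, with adjusted p from 0.31 to 0.663. The cholangiocyte and erythroid lists had 3 measured genes each and were not tested, with 3 of the former risen and 2 of the latter fallen.

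By limma, 6466 genes were higher and 3814 lower in NASH CD11c-negative cells (76.8% of those tested; 10463 at an unadjusted p under 0.05). The arrays of the groups did not overlap for 8586 genes, or 64.1%, where chance gives 0.794%. The named genes that passed did so at adjusted p of 0.000195 or less, and for all 73 of them no array of either group overlapped the other. The rule takes the largest rises and falls from genes passing without overlap, and members of function lists from passing genes. These values therefore describe the named genes and are no separate support. With slide as a block 695 genes were at least 2-fold higher and 832 lower, within slide 1 these were 658 and 823, and within slide 2 they were 705 and 811. With normexp they were 424 and 350 and with the stricter filter 525 and 460, so the larger share turned from lower to higher genes. The medians of the called lists within slides 1 and 2 were -1.48 and -1.53 for T cells, -1.34 and -1.88 for B cells and -1.18 and -1.12 for conventional dendritic cells. Genotype and diet differ together here, and the direction of small changes depends on scaling: the median gene lay 0.13 higher in NASH, against 0.00 with quantile normalization, where the share of calls that were higher went from 62.9% to 49.0%. The calls of lists are less certain than their counts, with 8 lists called when slide was a block (Kupffer cell identity, lipid-associated macrophage, endothelial, hepatocyte and neutrophil besides the 3), with 22 of 31 lists called when a preset correlation was used, and with no list called within slide 1 or when only the 2 groups were fitted. The B cell list was also not called within slide 2, and neither it nor the dendritic cell list was called with the stricter filter, with replicate number as a block or with this and slide together.

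**Figure D2:**
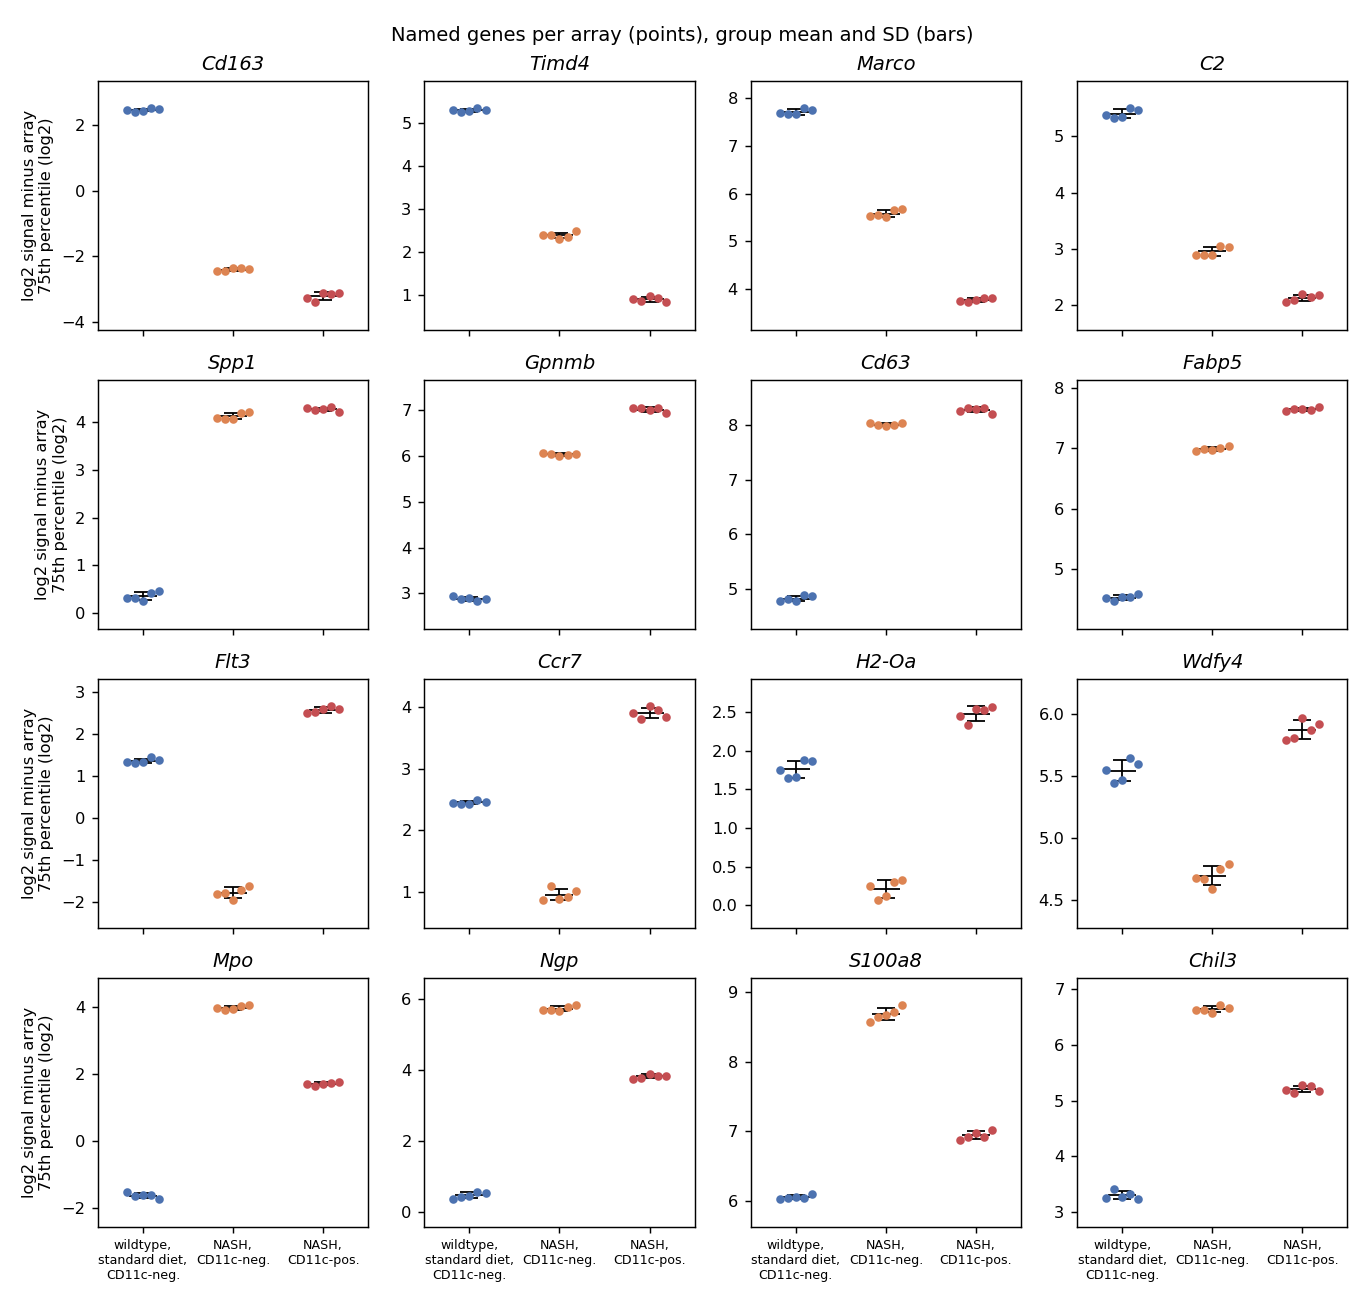
Level of 16 named genes on each array, as log2 signal minus the array's 75th percentile, with the group mean and SD over 5 arrays. Kupffer cell genes such as Cd163 stepped down across the groups (2.47, -2.41 and -3.22), Gpnmb stepped up, Flt3 was lowest in NASH CD11c-negative cells (-1.78), and Mpo was highest there (3.96).

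The comparison of CD11c-positive with CD11c-negative cells within NASH livers asks what sets the CD11c-positive macrophages apart in the same disease. Marco, a scavenger receptor gene of Kupffer cells, was 3.52-fold lower in the CD11c-positive cells (-1.82 ± 0.040 log2, n = 5 per group) and Timd4 was 2.78-fold lower (-1.48 ± 0.036). Atp6v0d2, which encodes a subunit of the vacuolar proton pump, was 2.87-fold higher (1.52 ± 0.048) and the macrophage elastase gene Mmp12 2.44-fold higher (1.29 ± 0.18). Flt3, a growth factor receptor gene of dendritic cells, was 20.4-fold higher (4.35 ± 0.054), and S100a8, a calcium-binding protein gene abundant in neutrophils, was 3.35-fold lower (-1.74 ± 0.040). Fewer genes differed than against wildtype, with 222 at least 2-fold higher and 159 at least 2-fold lower.

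By fitted value, the largest rises were all in genes barely measured in the CD11c-negative cells. Mycl, a Myc family gene of dendritic cells, Ffar4, a fatty acid receptor gene, Gpr141b and Htr7, a serotonin receptor gene, were at least 10.6-fold, 7.45-fold, 14.8-fold and 9.33-fold higher, being not well above background on any NASH CD11c-negative array. Gcsam, well above background on 1 of 5 CD11c-negative arrays, was at least 6.53-fold higher. Of the largest falls, Cxcl13, a B cell attractant, gave -2.70 ± 0.028, Wfdc21 -2.39 ± 0.026 and Prg2, the eosinophil major basic protein gene, -2.72 ± 0.054, with Prg2 well above background on 4 of 5 CD11c-positive arrays. The globin gene Hbb-bs, with 2 of 5 CD11c-positive arrays well above background, was at least 3.89-fold lower, and mesothelin (Msln) was at least 2.59-fold lower.

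Dendritic cell markers were higher in the CD11c-positive cells. Of 10 measured markers 9 rose and 1 did not pass (median 1.53, or 1.48 with Xcr1, not above background in CD11c-negative cells, at its bound; adjusted p = 0.017, limma camera). Ccr7 (2.95 ± 0.046), Cd209a (3.00 ± 0.051) and Wdfy4 (1.17 ± 0.050) rose with Flt3, and Batf3 gave 0.02 ± 0.041 (adjusted p = 0.64). Alongside these, the MHC class II modulators H2-Oa (2.27 ± 0.065) and H2-Ob (1.72 ± 0.042) rose, while H2-Ab1 fell (-0.44 ± 0.038, but -0.12 with quantile normalization) in a list with 3 genes higher, 5 lower and 5 not passed. Ccl22, not well above background on any CD11c-negative array, was at least 3.5-fold higher and Ccl17 rose (2.48 ± 0.20), both ligands of the receptor CCR4, whereas Ccl24 fell (-1.50 ± 0.034). The alternative activation list that holds them had 6 genes higher and 5 lower. Natural killer markers rose in 8 of 11 cases (median 1.31) and T cell markers in 11 of 13 (median 0.63, 0.18 with normexp), both at adjusted p = 0.104.

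Neutrophil markers were lower in the CD11c-positive cells, with 10 of 11 fallen and a median of -1.90 (adjusted p = 0.017, limma camera). S100a9 (-1.13 ± 0.035), Camp (-1.95 ± 0.045) and Ltf (-1.90 ± 0.039) fell with S100a8, and Csf3r gave 0.01 ± 0.027 (adjusted p = 0.803), passing only with normexp (0.09). In the same direction, Mmp9 (-1.68 ± 0.046) and Mmp8 (-1.35 ± 0.037), matrix metalloproteinase genes also expressed by neutrophils, fell in the matrix-remodelling list, while 10 of its 19 genes rose. Inflammatory cytokines and chemokines fell in 10 of 17 cases, among them Il6 (-1.27 ± 0.039) and Ccl7 (-1.19 ± 0.042), and Ccl5 rose (0.62 ± 0.065). Of the type I interferon genes 12 fell, including Zbp1 (-0.52 ± 0.023) and Irf7 (-0.37 ± 0.082), 2 rose, including Oas3 (0.22 ± 0.062), and 10 did not pass. Monocyte markers fell in 9 and rose in 4 of 13 cases. The matrix-remodelling, cytokine, interferon and monocyte lists did not pass as groups, with adjusted p from 0.162 to 0.85.

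Cell cycle genes were higher in the CD11c-positive cells, 26 of 28 (median 0.62, adjusted p = 0.0286, limma camera), with the mitotic motor gene Kif11 at 0.96 ± 0.038 and the topoisomerase gene Top2a at 0.96 ± 0.045. Cholesterol biosynthesis genes rose in 21 of 23 cases, among them Hmgcs1 (0.65 ± 0.060), and lipid-associated macrophage genes in 11 of 12, both at adjusted p = 0.104 (called with slide as a block). Trem2 gave -0.08 ± 0.037 (adjusted p = 0.0741) and turned to 0.10 with quantile normalization, and it passed with slide as a block (-0.10), replicate number as a block (-0.08) or these together (-0.09), within slide 2 (-0.105) and without NASH CD11c-negative replicate 1 (-0.10). Among liver X receptor targets 8 rose, including the stearoyl-CoA desaturase genes Scd2 (0.68 ± 0.036) and Scd1 (0.63 ± 0.039), and 5 fell, including Apoe (-0.43 ± 0.026), whose change was 0 with quantile normalization. Lysosomal genes rose in 13 and fell in 6 of 27 cases, with the cathepsin gene Ctsk at 1.02 ± 0.058, the cholesterol transporter gene Npc1 at 0.60 ± 0.041 and Ctss at -0.33 ± 0.051, which did not pass with quantile normalization (-0.08). In lipid uptake and storage 10 rose and 5 fell, with G0s2, an inhibitor of lipolysis, at -1.36 ± 0.056 and the oxidised lipoprotein receptor gene Olr1 at 0.77 ± 0.25 (0.33 with normexp). Without NASH CD11c-negative replicate 2, Olr1 stood at 0.65 (adjusted p = 0.0507 by limma, against 0.000372 to 0.0507 over its alternatives).

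Kupffer cell identity genes mostly fell in this comparison too, 16 of 18 (median -0.48, adjusted p = 0.135), and Il18bp rose slightly (0.14 ± 0.026). Complement genes fell in 9 of 11 cases, with C4b at -1.08 ± 0.034, C2 at -0.83 ± 0.047 and C5ar1 at 0.31 ± 0.027. Iron and haem genes fell in 7 of 13, among them Cd163 (-0.81 ± 0.049) and Ftl1 (-0.44 ± 0.038, -0.14 with quantile normalization), and Blvra rose (0.23 ± 0.028). Scavenger receptors fell in 11 of 20, and Mertk rose (0.46 ± 0.030). Toll-like receptor and inflammasome genes fell in 8 and rose in 3 of 19, with Tlr3 at 0.72 ± 0.036 and Cd14 at -0.47 ± 0.041. Changes under 1 log2 unit were seen in fatty acid oxidation (Acadl 0.25 ± 0.032, Cpt1a 0.23 ± 0.035, Hadh -0.13 ± 0.034), in glycolysis and hypoxia (Pfkp 0.53 ± 0.050, Pgam1 0.34 ± 0.043, Slc16a3 -0.27 ± 0.038), in the unfolded protein response (Asns 0.89 ± 0.036, Hyou1 0.28 ± 0.095, Herpud1 -0.20 ± 0.024) and in immediate early genes (Ier3 -0.49 ± 0.030, Fosb 0.42 ± 0.040). Of these 4 lists 9, 8, 8 and 11 members passed. Hyou1 no longer passed with normexp (0.13), within slide 1 (0.29), with array weights (0.24) or without NASH CD11c-negative replicate 3 or NASH CD11c-positive replicate 1 (0.26 each), nor Hadh with normexp (-0.06) or within slide 1 (-0.13). Liver sinusoidal endothelial markers fell in 12 of 15 and hepatocyte markers in 11 of 15 cases, and none of the lists of this paragraph passed as a group, although the Kupffer cell, iron and haem, endothelial and hepatocyte lists did with slide as a block.

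By limma 4008 genes were higher and 3108 lower in CD11c-positive cells (53.1% of those tested; 7781 at an unadjusted p under 0.05), and 5292 (39.5%) showed no overlap between the arrays, where chance gives 0.794%. The named genes that passed did so at adjusted p of 0.0234 or less, without overlap for 70 of 72, the exceptions being Oas3 and Hyou1. Here too the naming rule selects for this. With slide as a block 216 genes were at least 2-fold higher and 159 lower, within slide 1 these were 204 and 154, and within slide 2 they were 219 and 154. Within slides 1 and 2 the list medians were 1.55 and 1.47 for conventional dendritic cells, -1.90 and -1.94 for neutrophils and 0.61 and 0.58 for the cell cycle. With background correction by normexp the 2-fold counts were 83 and 75, and 155 of the 381 genes stayed at least 2-fold changed in the same direction. With slide as a block 9 lists were called, and a preset correlation called 17 of 31. No list was called with replicate number as a block or when only the 2 groups were fitted, the cell cycle list was not called with the stricter filter, and neither it nor the dendritic cell list was called within slide 1.

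The comparison of NASH CD11c-positive with wildtype cells spans disease and CD11c together. Timd4 was 20.8-fold lower (-4.38 ± 0.036 log2, n = 5 per group) and Cd163, well above background on 4 of 5 CD11c-positive arrays, 51.5-fold lower (-5.69 ± 0.049). Gpnmb, a glycoprotein gene of lipid-laden macrophages, was 17.5-fold higher (4.13 ± 0.028), Spp1 15.1-fold higher (3.92 ± 0.043) and Mmp12 12.3-fold higher (3.62 ± 0.18). Dcstamp, needed for the fusion of macrophages and osteoclasts, was 37.3-fold higher (5.22 ± 0.044). At least 2-fold changes were found for 891 genes upward and 940 downward.

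Further large rises were those of the cathepsin E gene Ctse (4.87 ± 0.031) and Dpys (4.86 ± 0.074), and Ctsj was at least 8.57-fold higher, not well above background on any wildtype array. Large falls were those of the lectin gene Cd209f (-5.65 ± 0.16), Ptgis (-5.05 ± 0.053) and Raver2 (-4.81 ± 0.19), and Adra2c was at least 15-fold lower. All 12 lipid-associated macrophage genes rose (median 2.87, or 2.70 relative to all genes), with Atp6v0d2 at 4.02 ± 0.048, and 17 of 18 Kupffer cell identity genes fell (median -1.57, or -1.73 relative to all genes). All 28 cell cycle genes rose, with Ccna2, a cyclin gene, at 1.22 ± 0.030 and Top2a at 1.20 ± 0.045, and 22 of 23 cholesterol biosynthesis genes rose, with Cyp51 at 1.20 ± 0.045 and Insig1 at -0.63 ± 0.053. The lists of lipid-associated macrophages, Kupffer cell identity and the cell cycle reached adjusted p = 0.0798 (each called with slide as a block), and cholesterol biosynthesis 0.275. Fdft1 gave 1.22 ± 0.046 on its brightest probe and -0.92 on another.

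Of the profibrotic and matrix-remodelling genes 16 of 19 rose, and Mmp9 fell (-0.51 ± 0.046). Inflammatory cytokines and chemokines rose in 12 and fell in 5 cases, with Cxcl1 at 2.29 ± 0.036 and Il6 at -2.97 ± 0.039. Complement genes went both ways (5 higher, 5 lower), with C2 at -3.28 ± 0.047, C4b at -2.33 ± 0.034 and C5ar1 at 1.49 ± 0.027, and a list median of 0.12 that turned to -0.16 with quantile normalization. In alternative activation 6 genes rose and 6 fell, with Ccl24 at -3.51 ± 0.034 and with Ccl22, well above background on 1 of 5 wildtype arrays, at least 3.61-fold higher. Class II presentation genes rose in 8 and fell in 4 of 13 cases, with H2-Aa at 1.28 ± 0.029, H2-DMb1 at 1.03 ± 0.041 and the costimulator gene Cd80 at -0.63 ± 0.051, whose other probe gave 0.19 (-0.22 for the mean of probes). Scavenger receptors rose in 8 and fell in 11 of 20, and iron and haem genes in 3 and 8 of 13, with Clec4e at 1.74 ± 0.064, Slc48a1 at -1.47 ± 0.038 and Blvra, of haem breakdown, at 0.95 ± 0.028. Toll-like receptor and inflammasome genes rose in 9 and fell in 5 of 19 (Tlr1 1.40 ± 0.038, Cd14 1.17 ± 0.041, Casp1 -0.39 ± 0.029), and interferon genes in 12 and 6 of 24 (Ifi44 1.55 ± 0.042, Bst2 0.71 ± 0.049 but 0.35 with quantile normalization, Oas2 -0.62 ± 0.028), and the medians of both lists, 0.08 and 0.13, turned to -0.05 and -0.02 with quantile normalization.

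Metabolic genes rose more often than they fell, but so did genes at large, with 6876 of 13390 higher and 3516 lower. The median gene lay 0.16 higher than in wildtype, or 0.05 with quantile normalization. Lipid uptake and storage rose in 14 and fell in 2 of 16 cases, with Olr1, well above background on 1 of 5 wildtype arrays, at least 4.63-fold higher, Fabp5 at 3.11 ± 0.026 and the lipolysis inhibitor gene G0s2 at -0.62 ± 0.056. Of the liver X receptor targets 8 rose and 6 fell, with Scd2 at 1.64 ± 0.036, Abca1 at 1.30 ± 0.028 and the apolipoprotein gene Apoc1 at -0.92 ± 0.028. Lysosomal genes rose in 21 of 27 (Ctsk 1.92 ± 0.058, Gla -0.21 ± 0.040), fatty acid oxidation genes in 16 of 18 (Slc25a20 0.91 ± 0.075, Acads 0.65 ± 0.059, Ehhadh -0.65 ± 0.12) and glycolysis and hypoxia genes in 17 of 18 (Pgam1 1.21 ± 0.043, Pgk1 1.08 ± 0.042, Hk1 -0.26 ± 0.048). The unfolded protein response rose in 12 of 16 cases, with Asns at 2.33 ± 0.036, Atf3 at 1.68 ± 0.036 and Chac1 at -1.20 ± 0.049, and immediate early and heat shock genes in 13 of 16, with Socs3 at 1.36 ± 0.036 and Ier3 at -0.16 ± 0.030. None of the lists of this and the preceding paragraph passed as a group, with adjusted p from 0.275 to 0.931.

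Among other cell types, the B cell and plasma cell list was the only 1 of 31 called against wildtype in the CD11c-positive cells, with 9 of 10 genes fallen (median -1.59, -1.55 with bounds, -0.88 with normexp, adjusted p = 0.0375, limma camera). Jchain (-1.87 ± 0.057) and Cd79b (-0.71 ± 0.066) fell. T cell markers fell in 12 of 13 (median -0.86, adjusted p = 0.0594), and that list was called with normexp (-0.67), no filter (-0.91), slide or replicate number as a block (-0.86 each), these together (-0.88) or array weights (-0.85), without wildtype replicate 4 (-0.83) and without NASH CD11c-negative replicate 3 or 4 (-0.86 each). Liver sinusoidal endothelial markers fell in 14 of 15 and hepatocyte markers in 13 of 15 (both 0.0798). Conventional dendritic cell markers rose in 7 and fell in 2 of 10 cases, with Flt3 at 1.21 ± 0.054 and Ccr7 at 1.45 ± 0.046, and neutrophil markers rose in 9 of 11 with Camp at 3.24 ± 0.045, at adjusted p = 0.668 and 0.3.

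By limma 6876 genes were higher and 3516 lower (77.6% of those tested; 10523 at an unadjusted p under 0.05), and 9274 (69.3%) showed no overlap between arrays, where chance gives 0.794%. All 71 named genes that passed did so at adjusted p of 0.000247 or less and without overlap, for which the naming rule again selects. With slide as a block 877 genes were at least 2-fold higher and 948 lower, within slide 1 these were 872 and 930, and within slide 2 they were 864 and 929. With normexp they were 579 and 504 and with the stricter filter 689 and 567, so here too the larger share turned. The B cell median was -1.58 within slide 1 and -1.75 within slide 2, and the list was called on neither. The median gene lay 0.16 higher than in wildtype, against 0.05 with quantile normalization, where the share of calls that were higher went from 66.2% to 54.4%. With slide as a block 8 lists were called (Kupffer cell identity, lipid-associated macrophage, cell cycle, iron and haem, T cell, endothelial and hepatocyte besides B cell). A preset correlation called 18 of 31 lists, and no list was called with the stricter filter, within slide 1, with probes averaged or when only the 2 groups were fitted.

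**Figure D3:**
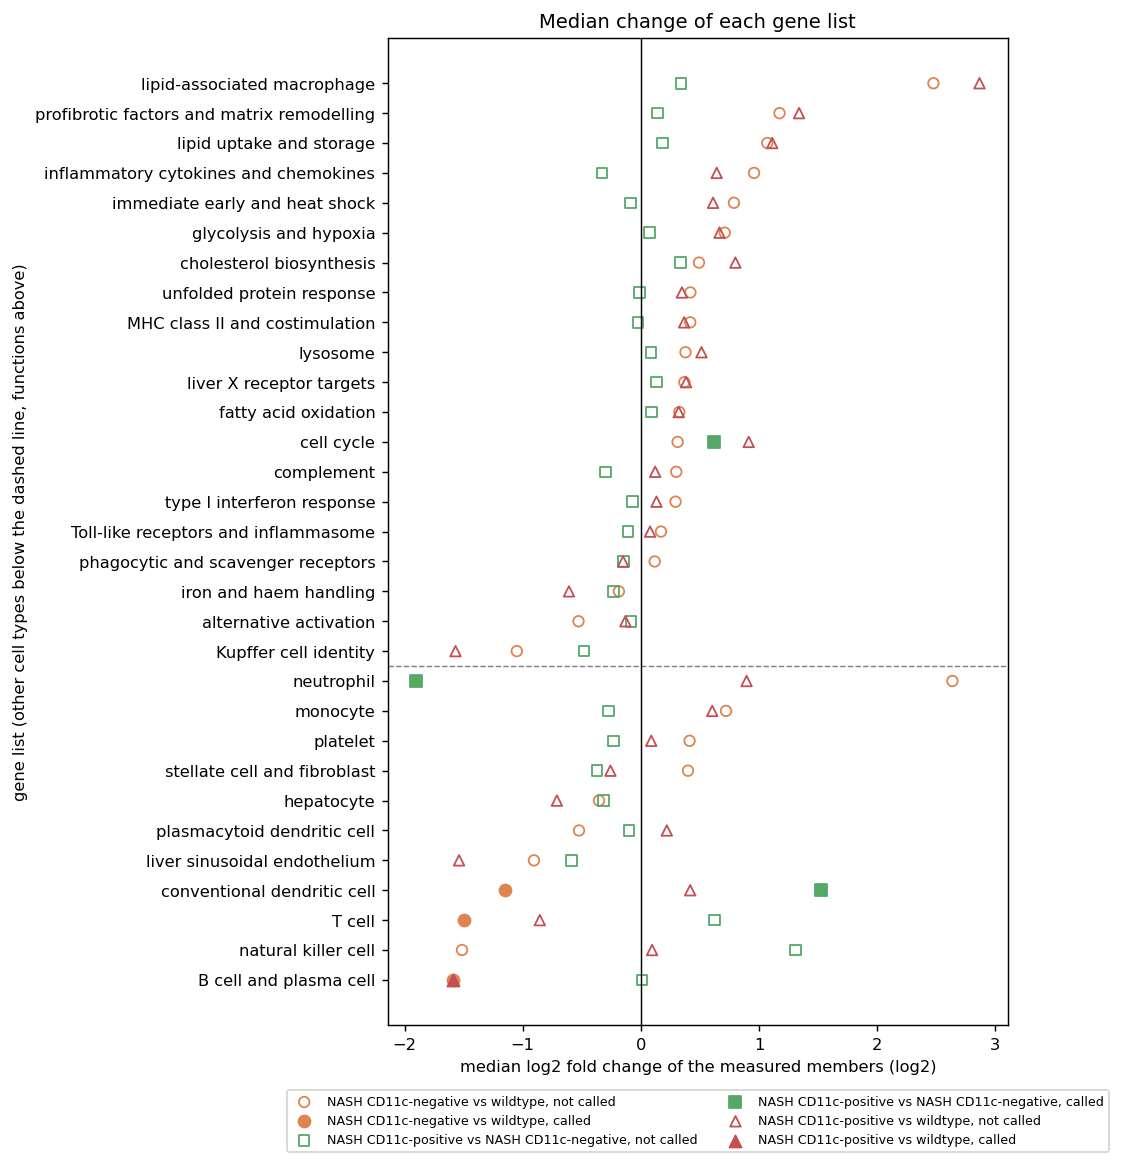
Median log2 fold change of the measured members of 31 gene lists in the 3 comparisons; filled symbols are lists called by limma camera with an estimated correlation, and the dashed line parts functions (above) from other cell types (below). Lipid-associated macrophage genes had medians of 2.48 and 2.87 against wildtype, and neutrophil genes 2.64 in the NASH CD11c-negative and 0.90 in the CD11c-positive cells.

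The changes against wildtype were largely shared by the NASH groups. Both had 558 genes at least 2-fold higher, among them Spp1, Gpnmb and Trem2, and 623 at least 2-fold lower, among them Cd163, Timd4 and C2, where independent lists would share 46.2 and 58.5. At the threshold of the test, 8479 genes changed the same way and 455 went in opposite directions. Among the 13378 genes with a value on every array 5608 rose and 2864 fell in both, against 3320.4 and 1001.5 for independent lists. Unchanged groups simulated against shared wildtype arrays gave 0.03 genes changed the same way on average and at most 3 in 100 draws. So few were fixed in advance, since almost no gene is called when none is changed. The simulated count therefore does not say what overlap to expect when most genes are called. With 2 or 3 of the wildtype arrays given to each comparison, the observed count was 7898 or 7706. This separates the controls only if the wildtype arrays came from separate RNA preparations, which is not known. Neither this count nor the covariance below with the arrays split can therefore decide the question. The log2 fold changes correlated across genes, which are not independent replicates, at 0.847, against a mean of 0.459 and a highest of 0.932 for the simulated unchanged groups, so the correlation does not set the shared changes apart from shared wildtype arrays. Their covariance was 0.483, against 0.00700 (at most 0.0241) simulated and 0.478 or 0.470 with the wildtype arrays split.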

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

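The tests of repeat measurements, of a lower share of macrophages and of neutrophil RNA were chosen after the results were seen. Of 438 sets of 5 values in a group (named genes and measures of array quality), 23, all of genes, held an array far from the other 4 (by Dixon's gap test), where chance gives about 1 in 20. Of those reported here, NASH CD11c-negative replicate 2 was the array for Ccl17 (-1.56, others -2.98 to -2.68), Hyou1 (-1.39, others -1.69 to -1.61) and Olr1 (-3.07, others -2.54 to -2.41). Wildtype replicate 2 was the array for C5ar1 (1.14), Ftl1 (9.55) and Mmp12 (0.54, others -0.65 to -0.46). Wildtype replicate 3 was the array for Cxcl1 (1.67), Cyp51 (-1.51) and Htr7 (-0.16, others -2.85 to -2.27), and NASH CD11c-negative replicate 5 for Ccna2 (1.29) and Msln (-2.56). The rest were Ctss (8.62) and Gla (8.14) on wildtype replicate 1, Ctse (-2.28) on wildtype replicate 5, Raver2 (-0.57, others -1.88 to -1.58) on NASH CD11c-negative replicate 1, Mmp8 (2.81) on NASH CD11c-negative replicate 3, Timp1 (-0.77) on NASH CD11c-positive replicate 2, and Cd209f (-2.90) and Npc1 (1.47) on NASH CD11c-positive replicate 5.

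Probes without a gene name also differed. Of 10833 such probes, 475 were at least 2-fold higher and 944 lower in NASH CD11c-negative than in wildtype cells, and 440 higher and 880 lower in NASH CD11c-positive than in wildtype cells. They were not analysed further here.

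The groups stood far apart in each comparison. With 2 groups in the fit, 10089, 6874 and 10548 genes changed (NASH CD11c-negative against wildtype, CD11c-positive against CD11c-negative, CD11c-positive against wildtype). In each case only 1 of 100 splits, the real one, gave as many, against at most 0, 1 and 67 genes in the others. The other splits leave the difference between the groups in the spread, so they call few genes whenever the groups stand apart. They therefore cannot exclude chance, and they say nothing of a chance difference between RNA preparations. The split with 67 genes follows the slides. Slide had an effect of its own, and a slide term in the fit passed for 6790 of 13390 genes. The slides do not account for the changes between groups, since every group lay on both slides. With slide as a block 10995, 8373 and 10916 genes were called, against 10280, 7116 and 10392 without it. Of the called genes 99.95%, 100% and 99.98% had the same sign on both slides, although they were called from the same arrays. The small spread within groups may come from repeat measurements of 1 RNA preparation per group: genes that vary between animals spread 0.97 times as widely as genes of like signal (95% interval 0.836 to 1.06, 57 genes), which leaves that explanation open, and separate pools of several mice with little variation between them remain untested.

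Dendritic, T and B cell markers were lower in NASH CD11c-negative cells, and dendritic cell markers higher in CD11c-positive than in CD11c-negative cells. A lower share of macrophages in the wildtype sort was tested by asking whether every list of other cells fell. The neutrophil list went the other way (median 2.64, 95% interval 1.22 to 5.19). This cannot decide the question, since neutrophil RNA can enter the NASH sort independently of other cells, so a lower share stays open. Hepatocyte markers had a median of -0.35 in NASH CD11c-negative against wildtype cells (-0.85 to -0.03, 15 markers). For these samples that argues against a 2-fold shift of hepatocyte RNA but not a smaller one. The 95% intervals in this section resample genes, not arrays, and do not measure the spread between samples. Conventional dendritic cells in the CD11c-positive gate may contribute to the higher dendritic cell markers there, with a median of 1.53 (0.561 to 3.15, 10 markers). A gate on high F4/80 is meant to remove most such cells, but the purity of the sorts was not tested here. The levels of Flt3 in wildtype, CD11c-negative and CD11c-positive cells were 1.36, -1.78 and 2.57, those of Ccr7 2.46, 0.96 and 3.90, and those of Batf3 4.47, 4.08 and 4.11. A change within macrophages, which the CD11c sort itself names, stays open.

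Neutrophil markers rose from wildtype to NASH CD11c-negative cells and fell from those to CD11c-positive cells. Neutrophil RNA in the NASH CD11c-negative sort may explain the fall, but the test left that open, with an SD of 0.694 between the falls of all 11 members (95% interval 0.291 to 0.906). The 7 genes at least 4-fold higher there than in wildtype were at -2.26 to -1.74 (median -1.91), although they were picked by their rise on the same arrays, and the other members were at -1.19 (Cxcr2), -1.13 (S100a9), -0.59 (Elane) and 0.01 (Csf3r), and macrophages and monocytes also express some of these genes. S100a9 stood at 7.71, 9.52 and 8.39 and S100a8 at 6.05, 8.68 and 6.94 in the 3 groups. A gate on high F4/80 is meant to remove most neutrophils, but the purity of the sorts was not tested here. A macrophage program of granule genes remains untested.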

How the results depend on the processing

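The counts of genes at least 2-fold changed under the alternatives were added after the results were seen. Of 222 values of named genes, 209 kept their direction and side of the threshold in every alternative that gave them a value, and of 93 list values 58 did. In this order the comparisons are NASH CD11c-negative with wildtype, CD11c-positive with CD11c-negative, and CD11c-positive with wildtype, which called 3, 3 and 1 lists. Lists called were 7, 7 and 6 with normexp, 9, 10 and 9 with quantile normalization, 5, 7 and 5 without a filter, 8, 9 and 8 with slide as a block, 0, 1 and 0 within slide 1, 7, 6 and 5 within slide 2, 1, 0 and 3 with replicate number as a block, 0, 0 and 0 with only the 2 groups compared, 22, 17 and 18 with a preset correlation and 30, 29 and 30 with fry. The stricter filter called 1 list in the first and 0 in the last comparison, replicate and slide blocks together 9 in the second and 6 in the last, the mean of probes 0 and array weights 2 in the last. The cause was not tested.

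Genes at least 2-fold higher and lower were 424 and 350, 83 and 75, and 579 and 504 with normexp, which adds an offset that shrinks folds of dim genes. The stricter filter tested 11798 genes, with 460 lower in the first, 105 higher and 85 lower in the second and 567 lower in the last comparison. Adding a 2-fold minimum to the test left 694 higher and 833 lower, 222 and 159, and 891 and 940. With quantile normalization Adgre1 reversed in the first comparison (-0.057, adjusted p = 0.0451 by limma, against 2.6e-09 to 0.0451 over its alternatives) and Trem2 in the second (0.10), and the cause was not tested.

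Leaving out 1 array gave 3 to 4, 3 to 3 and 1 to 2 lists. The adjusted p of the called lists over 29 alternatives ran from 0.0133 to 0.0824 (dendritic), 0.00323 to 0.0824 (T cell) and 0.0128 to 0.0824 (B cell) in the first, 0.00322 to 0.0918 (dendritic), 0.000179 to 0.0657 (neutrophil) and 0.000403 to 0.0918 (cell cycle) in the second and 0.00808 to 0.0836 (B cell) in the last comparison, none with a reversed direction. Replicate numbers do not settle whether the samples are paired. Of 15 pairs with the same number, 11 correlated above 0.1 (-0.198 to 0.373). In 8 of 15 the best match had the same number. Slide was not removed from these values, so fewer than 5 candidates may compete and no chance level is given. The negative pairs (-0.171 and -0.198), both of number 3, were the only ones on different slides, so a shared slide may raise the others. Signal over background limits dim genes: where a group had fewer than 3 arrays well above background, only bounds are given.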

Other observations

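The steps below were looked for after the results were seen. Of 222 genes at least 2-fold higher in NASH CD11c-positive than CD11c-negative cells, 48.2% had been at least 2-fold lower in CD11c-negative than in wildtype cells, where independent lists would share 13.8 genes. They included Flt3 (-3.14 then 4.35), the lymphocyte inhibitory receptor gene Btla (-3.28 then 4.05) and the retinoic acid synthesis gene Aldh1a2 (-1.35 then 3.02). Another 23 rose at both steps, against 11.5 for independent lists, among them Mmp12 (2.33 then 1.29), Siglecf, a sialic acid receptor gene (1.36 then 1.60), and Adam8, a metalloproteinase gene (1.31 then 1.35).

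Of 159 genes at least 2-fold lower in CD11c-positive than CD11c-negative cells, 77 had risen from wildtype to CD11c-negative cells, against 8.2 for independent lists, among them the granule protease genes Ctsg (5.05 then -2.21) and Prtn3 (4.46 then -2.04). Another 34 fell at both steps, against 9.9, among them Marco (-2.14 then -1.82), Fcna, a ficolin gene (-2.86 then -1.09), and Cxcl13 (-1.57 then -2.70). Both steps use the NASH CD11c-negative arrays, which favours genes that turn, and the examples were chosen after their values were seen.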
